A study of Homo sapiens with 12 samples.

How the data were processed

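The samples analysed here were 4 ChIP-seq libraries of H3K27me3 in T24 cells, an established human bladder cancer cell line. Per the labels, cells received DMSO (vehicle), 5 µM GSK-126, 5 µM fenretinide or both compounds at 5 µM each for 72 h, and chromatin was fixed with 1% formaldehyde for 10 min. Each condition had 1 library. The labels also list 4 input libraries and 4 RNA-seq libraries, which were not analysed here.

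The authors deposited a table of raw fragment counts for 273664 consensus intervals, and per the file headers it was made with featureCounts 2.0.1. The header gives counting of read pairs without strand, a minimum overlap fraction of 0.2, and counting of a fragment in every interval it overlaps. The authors also deposited a list of broad peaks for each library, with a peak score that had a minimum of 10 and no stated scale. Peaks were called with MACS2 2.1.0, per the submitters' processing notes, and annotated with HOMER, per the file headers. These deposited lists give the distance from each peak centre to the nearest transcription start site (TSS), the gene symbol and the annotation class. Peaks were called separately in each library, per the file headers, and the control used for calling was not given in the sources used here. The aligner was not given in the sources used here. The build was GRCh38 (hg38), per the submitters' processing notes, and coordinates are 1-based. All peaks lay inside a consensus interval, and the ends of all 273664 intervals equalled the outermost ends of their peaks, so intervals depend on what was called in the libraries compared.

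The libraries held 17133107 (vehicle), 16156194 (GSK-126), 18928836 (fenretinide) and 15812933 (combination) fragments in intervals. A count of 0 was given a floor of 3 counts per library for a lower bound on a fold. For each comparison, the ratio was the share of a library's interval fragments in 1 library divided by that in the other, with a 95% interval from the exact Clopper-Pearson binomial interval. Log2 ratios used a pseudocount of 0.5. An interval or gene was called higher at a ratio of at least 2 and lower at a ratio of at most 0.5, where the counting interval excluded 1. Intervals needed 20 fragments and genes 50 fragments in the 2 libraries together. Gene values summed the intervals that overlap a deposited peak whose nearest TSS was that gene and lay within 10 kb of the peak centre, which gave 18981 genes. Of these, 15657 matched a RefSeq symbol or synonym. An interval shared by several genes counted for each of them, as 2005 intervals did. Counting intervals and floors cover counting error only. They compare the libraries, not the conditions. Values over gene spans summed the intervals that overlap the RefSeq span of a gene with 5 kb on either side.

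The comparisons were each treated library against vehicle, and the combination against each single compound, 5 in all. No p-value was computed, since 1 library per condition gives no replicate check. For 16 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean fragments per gene in 20 bins, as a description of these libraries. A list was described as outside the random lists at or below percentile 2.5 or at or above percentile 97.5. Intervals of list medians come from order statistics over genes. Several lists had many members without an interval within 10 kb. Members with one were 12 of 39 HOX genes, 21 of 36 Polycomb genes, 15 of 38 apoptosis genes and 14 of 31 unfolded protein response genes. The comparisons, thresholds, lists and most alternatives were set before the data were examined.

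Named genes were chosen by rule. For each treated library against vehicle, they were the 10 largest rises and the 10 largest falls past the 2-fold rule with at least 100 fragments in the 2 libraries together, ranked by the counting bound nearest to 1, on chromosomes 1 to 22 and X. From each list, up to 2 members with the largest rise and up to 2 with the largest fall were added. RARB, CYP26A1, CDKN1A, CDKN2A, EZH2 and GATA3 were named whatever their values. The rule also asked for protein-coding genes where the deposited annotation gave a gene type, and it gave none, so pseudogenes and microRNA genes were kept. Zinc-finger genes (symbols starting with ZNF) were grouped only after their values were seen.

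The alternatives tried were DESeq2 1.42.0 size factors, edgeR 4.0.16 TMM factors, scaling to the 25% of intervals with the lowest fragments per kb over the 4 libraries (background scaling), other count minimums, a ratio of 1.5, other TSS distances, score and overlap limits for peaks, and others chosen after seeing the data. DESeq2 and edgeR served only to compute scaling factors. A correction for GC content and length was planned and not run, because no genome was used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

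The calling rule was tested on simulated Poisson counts, drawn from the pooled shares and the sizes of the real libraries, with 200 changed features, 50 at each fold size. Such counts vary by counting error only, so calls beyond those in simulated unchanged libraries need not come from a treatment. For genes, a 2-fold change was called for 32 of 50 with GSK-126 against vehicle (14728 genes), 26 with fenretinide against vehicle (14815 genes), 32 with the combination against vehicle (14713 genes), 22 with the combination against GSK-126 (13770 genes) and 25 with the combination against fenretinide (14630 genes). A 3-fold change was called for 50, 49, 49, 45 and 50 genes, and a 1.5-fold change for 2, 0, 1, 3 and 0, in the same order. Unchanged genes called numbered 14 of 14529, 14 of 14619, 14 of 14513, 23 of 13572 and 20 of 14430. For intervals, a 2-fold change was called for 20 of 50 with GSK-126 against vehicle (157404 intervals), 18 with fenretinide against vehicle (159562 intervals), 21 with the combination against vehicle (158628 intervals), 23 with the combination against GSK-126 (153121 intervals) and 23 with the combination against fenretinide (164337 intervals). Unchanged intervals called numbered 2133 of 157211, 2253 of 159369, 2163 of 158433, 2200 of 152924 and 2399 of 164142. In lists of 30 genes, lowering all members 1.5-fold placed 50 of 50 lists outside the random lists in each comparison with vehicle, against 2 of 50 unchanged lists for GSK-126, 2 of 50 for fenretinide and 0 of 50 for the combination. All other genes were unchanged in these list simulations, so their random lists spread by counting error only. Real random lists spread more, and a list lowered as far may stay inside them. Urothelial markers with GSK-126, at a median of -1.24 against -0.82 for random lists, lay at percentile 6.23.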

Results

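H3K27me3, the repressive histone mark that EZH2 places as part of a Polycomb complex, was profiled by ChIP-seq in T24 bladder cancer cells after 72 h with vehicle, the EZH2 inhibitor GSK-126, the synthetic retinoid fenretinide or both. The series asks how retinoids and EZH2 inhibition act together in these cells. Each condition had 1 library, so no difference below has a replicate check. The libraries held 15812933 to 18928836 fragments in 273664 intervals that covered 1296 Mb, with 13.2 (vehicle), 12.5 (GSK-126), 14.6 (fenretinide) and 12.2 (combination) fragments per kb. Ratios below are ratios of library shares, and brackets hold the 95% counting interval. No label names a spike-in, so a rise or fall below is one in library share, which need not be a gain or loss in the amount of the mark.

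The deposited lists held 212277 peaks over 703 Mb for vehicle, 217751 over 700 Mb for GSK-126, 234815 over 746 Mb for fenretinide and 274393 over 829 Mb for the combination. Median deposited peak scores were 20, 17, 19 and 15. Peaks at promoters took 1.36% of the peak length with vehicle, 0.988% with GSK-126, 1.08% with fenretinide and 0.928% with the combination. Of the vehicle peaks, 61.5% overlapped a GSK-126 peak, 79.1% a fenretinide peak and 72.5% a combination peak by at least 1 bp. Combination peaks overlapped 81.5% of the GSK-126 peaks and 72.6% of the fenretinide peaks. The 70517 intervals with a peak in all 4 libraries made up 71.7% of the interval length.

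GSK-126 against vehicle asked where an EZH2 inhibitor changed the distribution of the mark. In library share, the mark fell near all 9 measured HOX genes, 28 of 38 WNT, BMP and growth factor ligands, 21 of 36 blood genes and 11 of 13 Polycomb genes, and rose over 28 of 43 clustered protocadherins and 244 of 349 zinc-finger genes. Near SMAD7, an inhibitor of TGF-beta signalling, 115 vehicle fragments became 7, a ratio of 0.0646 (0.0254 to 0.137). Over ZNF891, a zinc-finger gene, 27 fragments became 1474, a ratio of 57.9 (39.6 to 88.2). Near genes, 1698 of 14725 were called higher and 6096 lower, and with scaling to background-like intervals (below, background scaling) 1067 were higher and 10106 lower. The median gene had a log2 ratio of -0.79, and the list medians below stand beside that value.

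The largest falls with GSK-126 included CCDC183 (ratio 0.0869, 0.0477 to 0.147), YTHDF1, a reader of methylated RNA (0.132, 0.0850 to 0.197), NXPH4, a secreted neuronal glycoprotein (0.136, 0.0891 to 0.201), PWP1 (0.146, 0.105 to 0.2) and ASIC4 of the acid-sensing ion channel family (0.160, 0.132 to 0.193). AC105053.3 went from 230 to 28 fragments. ESPN, an actin-bundling protein gene, the transcriptional repressor gene HES2 and MIR4252 shared an interval on chromosome 1 from 6406006 to 6437309, where 1477 fragments became 251, a ratio of 0.180 (0.157 to 0.206). The SMAD7 interval lay on chromosome 18 from 48953449 to 48954917.

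The largest rises were mostly zinc-finger genes. ZNF845 rose from 14 to 673 fragments, ZNF7 from 16 to 727, ZNF124 from 17 to 754, ZNF615 from 16 to 690 and the pseudogene LOC100289333 from 41 to 1544, with ratios of 51.0, 48.2, 47.0, 45.7 and 39.9. ZNF436 rose from 3 to 227 fragments, a ratio of 80.2 with a lower counting bound of 27.1, and ZNF816 with ZNF321P, which share an interval, from 3 to 257, a ratio of 90.8 (30.7 to 443). The pseudogene DUX4L4 had 0 vehicle and 105 GSK-126 fragments, at least 37.1-fold higher. The ZNF891 interval lay in an intron on chromosome 12 from 133082139 to 133129440. Taken as a set after their values were seen, 244 of 349 ZNF genes were higher, 37 lower and 68 neither, with a median log2 ratio of 2.23. Neighbouring ZNF genes share intervals, and 267 groups that share none had a median of 2.03 (1.69 to 2.37). On chromosome 19, the 195 ZNF genes had a median of 3.08 and the other 780 genes -1.15.

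**Figure D1:**
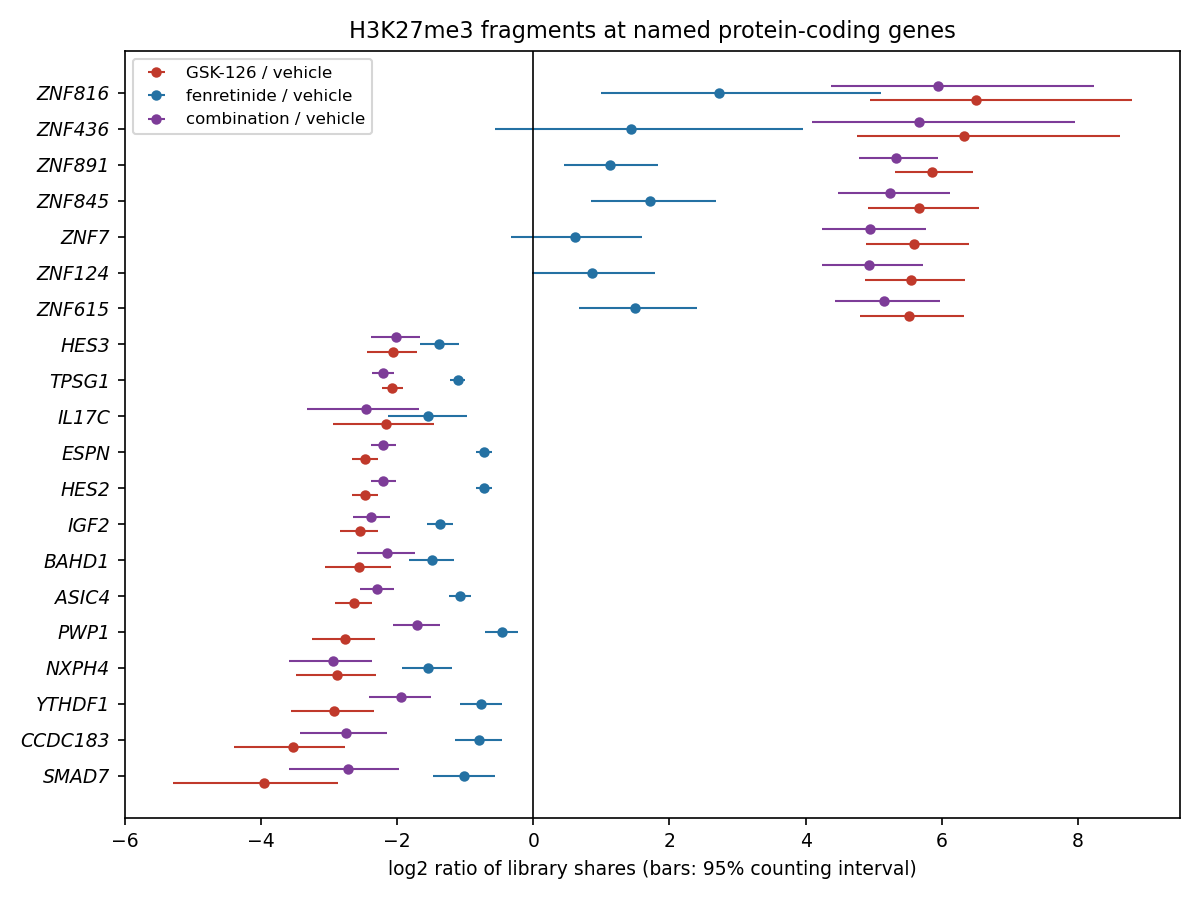
Log2 ratios of H3K27me3 library shares for protein-coding genes among the largest rises and falls with GSK-126 and the largest falls with fenretinide, for each treated library against vehicle (1 library each). Bars are 95% counting intervals, ESPN and HES2 share an interval, and GSK-126 and combination points lie close together while fenretinide points lie nearer 0.

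HOX genes set position along the body axis, and 9 of the 39 written were measured. All 9 fell with GSK-126 (median log2 -1.84, percentile 0.160 of matched random lists), among them HOXD11 (0.203, 0.115 to 0.339) and HOXD13 (0.207, 0.147 to 0.288). Of 38 WNT, BMP and growth factor ligand genes, 28 fell, none rose and 10 did neither (median -1.42, percentile 0.05), with CHRD, a BMP antagonist, at 0.206 and NODAL at 0.235. Of 13 Polycomb subunit genes, 11 fell and 2 did neither (median -1.90, below all 10000 random lists). Over gene spans, 5 of 22 rose, 11 fell and 6 did neither (median -1.16, -1.77 to -0.0089), and without a limit on TSS distance the median of -1.12 lay inside the random lists (percentile 2.56). Within 2 kb of the TSS no Polycomb gene was measured. EED, a core partner of EZH2, was at 0.184 (0.109 to 0.298) and C17orf96 at 0.173. Of 36 blood lineage genes, 21 fell, 2 rose and 13 did neither (median -1.40, percentile 0.01). CD79A of the B cell receptor was at 0.149, while CD14, a receptor for bacterial lipopolysaccharide, rose to 3.54 (2.61 to 4.86) and the erythroid factor gene KLF1 to 2.69.

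Clustered protocadherins, neuronal adhesion genes on chromosome 5, went the other way: 28 of 43 rose, none fell and 15 did neither (median 1.5, above all random lists). These genes share intervals, 23 for 44 genes, so they are not independent. PCDHGA12 was at 8.92 (5.97 to 13.8) and PCDHB15 at 7.85 (7.11 to 8.69). Of 47 neuronal channel and synapse genes, 10 rose, 12 fell and 25 did neither (median -0.25, percentile 99.5), with NLGN1, a synaptic adhesion gene, at 4.45 and the glutamate receptor gene GRIA1 at 0.260. That median lay inside the random lists within 2 kb of the TSS (percentile 92.2) and without a distance limit (86.6). Of 71 neural and developmental transcription factor genes, 7 rose, 28 fell and 36 did neither (median -0.66, percentile 69.3). PAX2 was at 0.219 (0.197 to 0.242) and SOX3 at 7.28 (5.81 to 9.21).

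Of 20 urothelial and luminal markers, 12 fell, none rose and 8 did neither (median -1.24, percentile 6.23, against 2.4 within 2 kb of the TSS), with UPK1A, which encodes a protein of the urothelial surface, at 0.245 and GRHL3 at 0.246. Of 17 cell cycle inhibitors and tumour suppressors, 10 fell and 7 did neither (median -1.30, percentile 3.32, and -0.12 without a distance limit), with KLF4 at 0.130 and SFRP5, a WNT inhibitor, at 0.248. Of 35 antigen presentation and interferon genes, 21 fell and 14 did neither (median -1.22, percentile 2.52, against 1.59 when random lists were matched on fragments per kb and 1.22 without a distance limit), with ULBP2, a ligand of natural killer cells, at 0.241 and PSMB9 of the immunoproteasome at 0.260. Of 28 retinoid pathway genes, 9 fell, 1 rose and 18 did neither (median -0.73, percentile 64.2). RARG, a retinoic acid receptor gene, fell to 0.213 and STRA6, the receptor for vitamin A uptake, to 0.265, while the retinol dehydrogenase gene RDH12 rose to 2.83.

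Basal and squamous markers split into 1 higher, 4 lower and 19 neither (median -0.77, percentile 40.1), with KRT17 at 0.299 and SERPINB3 going from 13 to 49 fragments. Mesenchymal markers split into 1, 3 and 8 (median -0.27, percentile 90.2), with SNAI1 at 0.272 and CDH11 at 2.14. Apoptosis genes split into 0, 5 and 5 (median -1.06, percentile 26.4, and -0.40 without a distance limit), with BIK, a pro-apoptotic gene, at 0.184. Unfolded protein response genes split into 0, 4 and 4 (median -0.95, percentile 37.6, the 1 gene within 2 kb being at -2.63), with the stress factor gene ATF3 at 0.154. All 4 measured housekeeping genes, of 32 written, fell (median -1.55, percentile 8.78), with TFRC, the transferrin receptor gene, at 0.275. Of the genes named in advance, RARB was at 0.530 (0.370 to 0.752), CYP26A1 at 0.562 (0.415 to 0.757) and GATA3 at 0.761 (0.546 to 1.06), and none of these passed the rule. Over its gene span of 142 intervals RARB went the other way, at 1.14 (1.10 to 1.18). CDKN1A, CDKN2A and EZH2 had no interval within 10 kb.

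Across intervals, 40688 of 156925 were higher and 33927 lower with GSK-126, against 20175 and 66793 with background scaling. Of 1458 promoter intervals, 172 were higher and 600 lower, and of 98616 intergenic intervals 27703 were higher and 18912 lower. Background scaling moved log2 ratios by -0.77 for GSK-126, -0.13 for fenretinide and -0.81 for the combination against vehicle, and by -0.68 for the combination against fenretinide. The ZNF genes kept a median above 0 under that scaling (1.47, or 1.27 over the 267 groups of ZNF genes that share no interval), with 211 of 349 higher and 68 lower.

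**Figure D2:**
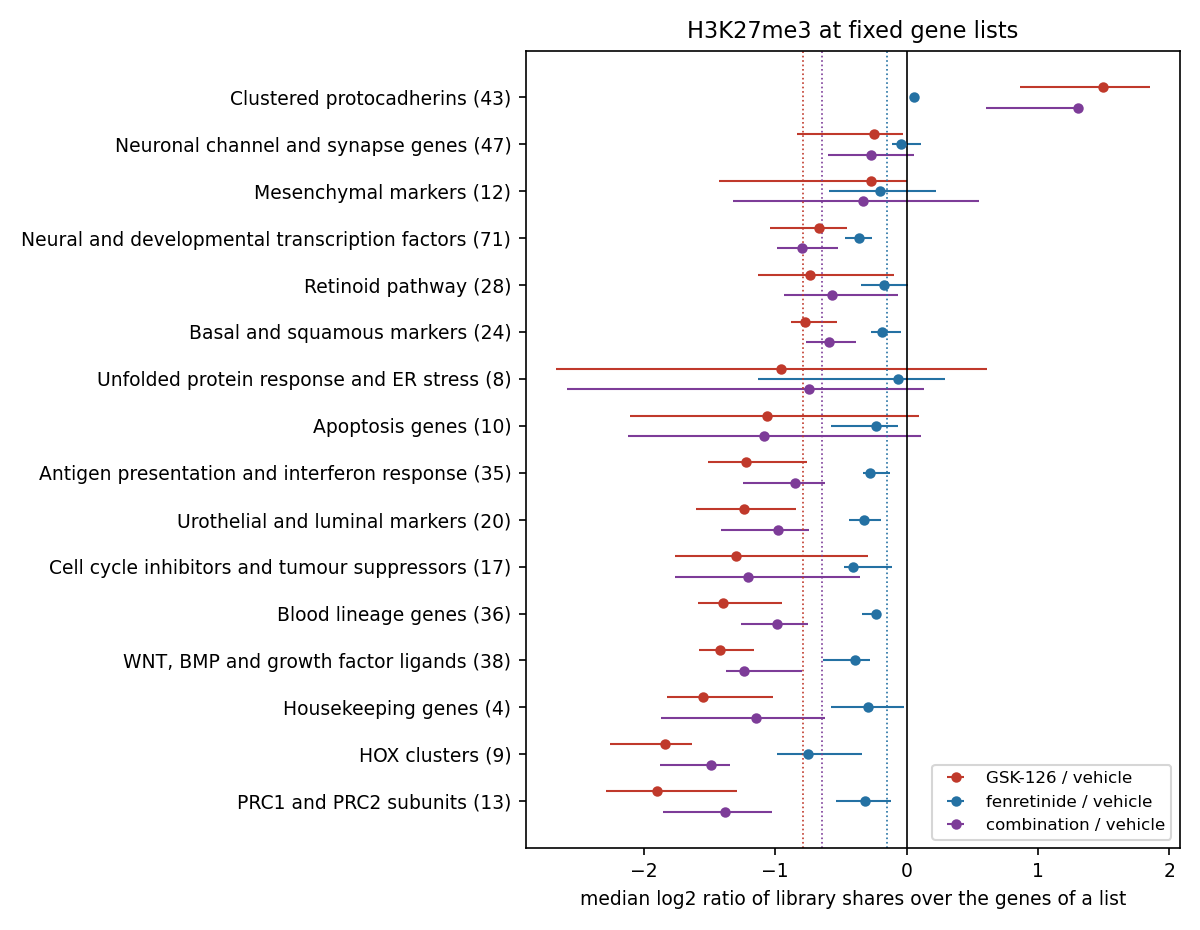
Median log2 ratio of H3K27me3 library shares over the measured genes of 16 fixed lists (number measured with GSK-126 in brackets), for each treated library against vehicle, with bars for order-statistic intervals over genes and dotted lines at the median of all genes. HOX and Polycomb lists sit lowest with GSK-126 and the protocadherins highest, and the fenretinide protocadherin median of 0.06 turns to -0.0652 with DESeq2, -0.0590 with TMM and -0.0758 with background scaling.

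Fenretinide against vehicle asked whether a retinoid alone moved the mark. Its changes were smaller: 50 of 14818 genes were higher and 223 lower, and the median gene was at -0.15. The mark fell near NXPH4, from 226 to 85 fragments (0.340, 0.262 to 0.439), near BAHD1, which encodes a heterochromatin protein (0.355, 0.281 to 0.446), and at IGF2, a growth factor gene (0.388, 0.340 to 0.442). The IGF2 interval, shared with IGF2-AS, lay on chromosome 11 from 2131497 to 2151005 and went from 766 to 328 fragments. HOX, developmental and WNT lists had lower medians than matched random lists. The cell cycle median was also lower, but not at each TSS distance tried (below). Few genes of these lists passed the 2-fold rule.

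Further falls with fenretinide were HES3 (0.384, 0.314 to 0.467), TPSG1, a tryptase gene (0.462, 0.427 to 0.501), the cytokine gene IL17C (0.343, 0.227 to 0.508), MIR4462 (0.310) and LOC100505585 with LOC390937, which share an interval (0.423). The largest rises were MIR4273 from 73 to 223 fragments (2.76, 2.11 to 3.65), ZNF716 from 56 to 162 (2.62, 1.92 to 3.61), the olfactory receptor gene OR4D5 (2.19), MIR490 (2.05), ZNF701 (2.03) and the casein gene CSN1S1 (2.02, 1.48 to 2.78). LOC101929740 (2.24), AC097500.2 (2.14), LOC102723561 (2.04) and LOC100289333 (2.01) also rose. CYP26A1, whose product degrades retinoic acid, fell to 0.494 (0.365 to 0.663), while RARB was at 0.987 (0.745 to 1.31), or 1.14 (1.10 to 1.18) over its gene span, and GATA3 at 0.797 (0.584 to 1.09).

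HOX genes had a median of -0.75 with fenretinide, below all random lists, with 1 of 10 called lower and 9 neither; HOXD11 was the called gene (0.472, 0.327 to 0.673). Neural and developmental transcription factor genes had a median of -0.36, below all random lists, with 0 of 69 called. WNT, BMP and growth factor ligands had a median of -0.39 (percentile 0.01), and 2 of 39 fell, WNT4 (0.415) and WNT2B (0.427). Cell cycle inhibitors and tumour suppressors had a median of -0.41 (percentile 0.170), with KLF4 lower (0.443) among 18, and lay inside the random lists within 2 kb of the TSS (percentile 2.85) and without a distance limit (5.78). Urothelial and luminal markers had a median of -0.33 (percentile 2.5, against 3.12 when random lists were matched on fragments per kb, 8.02 within 2 kb and 12.4 without a distance limit). Of 19 such genes FGFR3, a receptor tyrosine kinase gene, fell (0.410, 0.327 to 0.510). Protocadherins had a median of 0.06 (percentile 99.99, and 97.4 when matched on fragments per kb), which turned to -0.0652, -0.0590 and -0.0758 with DESeq2, TMM and background scaling, and 0 of 43 were called. Their shared intervals make such percentiles look more extreme than independent genes would. The 307 ZNF genes, grouped after their values were seen, had a median of 0.14 (0.09 to 0.20), with 10 higher, 1 lower and 296 neither. Their median was 0.07 (0.01 to 0.14) over 228 groups that share no interval. With background scaling the 307 genes had 0.0029 (-0.04 to 0.06).

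The other lists lay inside the random lists. Retinoid pathway genes had a median of -0.17 (percentile 48.9) with 2 of 29 lower, STRA6 (0.472) and CYP26A1. Blood genes had -0.23 (percentile 5.42) with 3 of 36 lower, CD79A (0.492) and HBA2 (0.495) among them. Antigen presentation genes had -0.27 (percentile 3.47) with 0 of 36 called, and Polycomb genes -0.32 (percentile 9.57) with 0 of 16, CBX8 being at 0.501. Neuronal genes had -0.04 (percentile 97.2), with SYN1, a synaptic vesicle gene, lower (0.453) among 46, and their median turned to 0.15 over gene spans and to 0.17 without a distance limit (percentile 99.99). Basal markers had -0.19 (percentile 18.3) with TFAP2A lower (0.377) among 23, mesenchymal markers -0.20 (percentile 38.8, but a median of -0.79 at percentile 0.110 for the 8 within 2 kb) with SNAI1 lower (0.453) among 14, and unfolded protein response genes -0.07 (percentile 75.6, the 1 gene within 2 kb being at -1.03) with ATF3 lower (0.455) among 8. Without a distance limit, Polycomb genes (percentile 1.66) and blood genes (0.2) lay outside the random lists. Apoptosis genes had -0.23 (percentile 29.3) with 0 of 11 called and housekeeping genes -0.30 (percentile 30.6) with 0 of 5, which turned to 0.0175 over the gene spans of 2 genes.

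With DESeq2, TMM and background scaling the gene calls were 29 higher and 373 lower, 31 and 366, and 27 and 391. Across intervals 5266 of 159127 were higher and 3432 lower, while simulated unchanged libraries, which vary by counting error only, gave 2253 calls. With DESeq2, TMM and background scaling the split was 3256 and 5229, 3281 and 5122, and 3100 and 5386. Of 1540 promoter intervals 22 were higher and 132 lower, and of 99182 intergenic intervals 3233 were higher and 1837 lower.

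The combination against vehicle asked what both compounds together did. HOX, WNT and Polycomb lists had lower medians than matched random lists and protocadherins a higher one, as with GSK-126 alone. No Polycomb gene was measured within 2 kb of the TSS. Blood and cell cycle medians were also lower, but not at each TSS distance tried (below). CA11, a carbonic anhydrase-related gene, went from 97 to 7 fragments (0.0782, 0.0306 to 0.167), BIK from 144 to 16 (0.120, 0.0670 to 0.202) and NXPH4 from 226 to 27 (0.129, 0.0835 to 0.193). ZNF891 rose to 40.2 (27.5 to 61.4) and ZNF845 to 37.8 (22.3 to 69.7). Genes called numbered 1453 higher and 4842 lower of 14736, or 756 and 10196 with background scaling, and the median gene was at -0.64.

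SAMD11, with LOC100130417 and LOC101928801 in the same interval on chromosome 1 from 910038 to 944188, went from 1352 to 191 fragments (0.153, 0.131 to 0.178). CCDC183 and the orphan receptor gene GPR20 were both at 0.148, LSP1, an actin-binding protein gene of leukocytes, at 0.172 and IGF2 at 0.192 (0.159 to 0.231). Among the rises, ZNF816 with ZNF321P was at 61.8 (20.8 to 302), ZNF615 at 35.6, ZNF254 at 34.4, LOC100289333 at 31.8, ZNF7 at 30.9, ZNF124 at 30.7 and ZNF570 at 22.8. CYP26A1 fell to 0.443 (0.317 to 0.613), and RARB (0.672, 0.481 to 0.931, but 1.21, 1.17 to 1.26, over its gene span) and GATA3 (0.813, 0.586 to 1.12) did not pass.

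All 9 HOX genes fell with the combination (median -1.49, percentile 0.425), as did 24 of 39 WNT and growth factor ligand genes (median -1.24, percentile 0.01), WNT10B being at 0.0914 and WNT4 at 0.211. Of 18 cell cycle inhibitors 11 fell (median -1.21, percentile 0.590), TIMP2 at 0.212 and KLF4 at 0.221, but the median was -0.17 without a distance limit (percentile 77.2) and lay inside the random lists within 2 kb (percentile 4.64). Of 13 Polycomb genes 11 fell (median -1.38, percentile 0.550), CBX8 at 0.217 and CBX2 at 0.246. Over gene spans, 5 of 22 Polycomb genes rose, 10 fell and 7 did neither (median -0.90). Of 36 blood genes 18 fell and 1 rose (median -0.98, percentile 0.830), CD79A at 0.0760 and CD14 at 3.27. Protocadherins had 26 of 43 higher and none lower (median 1.31, above all random lists), PCDHB15 at 5.95. Neuronal genes had 7 higher, 9 lower and 31 neither (median -0.27, percentile 99.1), CDH18 being at 4.33. Within 2 kb of the TSS neuronal genes (percentile 84.5) and blood genes (8.02) lay inside the random lists, as did neuronal genes without a distance limit (84.0).

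Developmental transcription factor genes split into 3 higher, 25 lower and 41 neither (median -0.80, percentile 3.23), with GSX2 at 0.218 and HAND2 at 3.02. Urothelial markers had 9 of 20 lower (median -0.97, percentile 9.17), with FGFR3 at 0.268, and basal markers 1 higher and 3 lower of 24 (median -0.59, percentile 50.8), with TFAP2A at 0.0903. Antigen presentation genes had 15 of 35 lower (median -0.85, percentile 15.3, against 1.64 within 2 kb and 1.25 without a distance limit) and retinoid genes 1 higher and 7 lower of 29 (median -0.57, percentile 70.1), with STRA6 at 0.224. Mesenchymal markers had 3 of 13 lower (median -0.33, percentile 86.2), apoptosis genes 5 of 10 (median -1.09, percentile 7.98), unfolded protein response genes 3 of 8 (median -0.74, percentile 40.5, the 1 gene within 2 kb being at -2.47) and housekeeping genes 3 of 4 (median -1.15, percentile 18.2).

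Across intervals 38127 of 158263 were higher and 24939 lower with the combination, against 16254 and 64420 with background scaling. Comparisons that share the vehicle library share its chance error. GSK-126 and the combination both lowered 4589 genes, where independent lists would share 2009, and both raised 1389, where independent lists would share 156. Their log2 ratios across genes had r = 0.971 against 0.492 in simulated unchanged libraries, and a covariance of 1.44 against 0.0193. GSK-126 and fenretinide both lowered 178 genes against 87.9 for independent lists, and both raised 41 against 3.62, with r = 0.633 against 0.492 and a covariance of 0.253 against 0.0178. Fenretinide and the combination both lowered 181 genes against 70.4 and both raised 40 against 3.17, with r = 0.673 against 0.515 and a covariance of 0.235 against 0.0192. In the simulated unchanged libraries, these pairs shared 1 lower and 2 higher genes, 1 and 2, and 0 and 4, in the same order. With the vehicle fragments split at random so that each comparison had its own part, r was 0.943, 0.557 and 0.585 and the covariance 1.42, 0.237 and 0.219. A deviation of the vehicle culture itself stays in both parts, so part of each excess may come from the shared vehicle library.

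The combination against GSK-126 asked what fenretinide added to EZH2 inhibition. Few genes differed: 61 of 13777 were higher and 69 lower, against 19 and 106 with DESeq2, 22 and 104 with TMM, and 43 and 83 with background scaling. Named after their values were seen, PWP1 was higher in the combination than with GSK-126 (2.09, 1.45 to 3.05), as were C17orf96 (2.29, 1.34 to 4.03) and AC105053.3 (2.59, 1.65 to 4.17), and SIM2 (0.422, 0.256 to 0.676) and DUX4L4 (0.477, 0.333 to 0.675) were lower. Antigen presentation genes had a median of 0.23 (percentile 98.9, and 93.6 within 2 kb of the TSS), protocadherins -0.22 (below all random lists) and developmental transcription factor genes -0.02 (percentile 0.180, and 2.99 when matched on fragments per kb), which turned to 0.0437 without a limit on TSS distance and to 0.0108 over gene spans. The 351 ZNF genes had a median of -0.27, with 0 higher and 2 lower.

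In the remaining lists, medians for the combination against GSK-126 lay inside the random lists, although mesenchymal markers were at percentile 1.02 when matched on fragments per kb, blood genes at 98.4 within 2 kb of the TSS, and without a distance limit HOX genes at 97.6 and Polycomb genes at 98.2. They were 0.29 for HOX genes, 0.17 for WNT and growth factor ligands, 0.21 for Polycomb genes, -0.01 for neuronal genes, -0.10 for mesenchymal markers, -0.02 for apoptosis genes and 0.29 for housekeeping genes. Neuronal genes turned to 0.0206 over gene spans and 0.000369 without a distance limit, mesenchymal markers to 0.0838 without a limit, and apoptosis genes to 0.101 within 2 kb and 0.0229 without a limit. Medians of 0.09 for urothelial, retinoid and unfolded protein response genes and 0.10 for blood genes turned negative with DESeq2 and TMM scaling, 0.11 for basal markers turned negative with DESeq2 only, and 0.02 for cell cycle inhibitors turned negative with all 3 other scalings and within 2 kb (-0.0104). Retinoid genes also turned to -0.0185 within 2 kb and unfolded protein response genes to -0.0721 without a limit. Intervals called numbered 3785 higher and 2770 lower of 152518, against 2200 calls in simulated unchanged libraries, which vary by counting error only. The split was 2211 and 4050 with DESeq2 and 2357 and 3928 with TMM.

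The combination against fenretinide asked what GSK-126 added to fenretinide, and 1380 of 14631 genes were higher and 2739 lower, or 690 and 8723 with background scaling. Polycomb genes (9 of 13 lower, median -1.14, percentile 0.0900), WNT and growth factor ligands (9 of 37 lower, median -0.79, percentile 0.390) and blood genes (7 of 35 lower, median -0.72, percentile 1.25, against 6.42 within 2 kb of the TSS) lay below the random lists. Protocadherins lay above them (26 of 43 higher, median 1.24, and 0.58 over gene spans). ZNF genes had 231 of 344 higher and 23 lower, with a median of 1.71, or 175 and 59 with a median of 1.03 under background scaling. HOX genes had 3 of 9 lower (median -0.79, percentile 13.5). Over gene spans, 5 of 21 Polycomb genes were higher, 6 lower and 10 neither (median -0.69). Antigen presentation genes lay below the random lists without a distance limit (percentile 1.89) and developmental transcription factor genes above them within 2 kb (97.8). Intervals split into 30524 higher and 19862 lower of 163891, or 11894 and 60310 with background scaling.

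Whether each compound moved the same intervals on both backgrounds was asked with pairs of ratios that share no library. Across 147129 intervals, the GSK-126 ratio without and with fenretinide had r = 0.845 (Spearman rho 0.843), and 85.1% of intervals moved in the same direction. Across 127725 intervals, the fenretinide ratio without and with GSK-126 had r = -0.126 (rho -0.165), with 43.8% in the same direction. Intervals are not independent replicates, so these values carry no p-value.

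**Figure D3:**
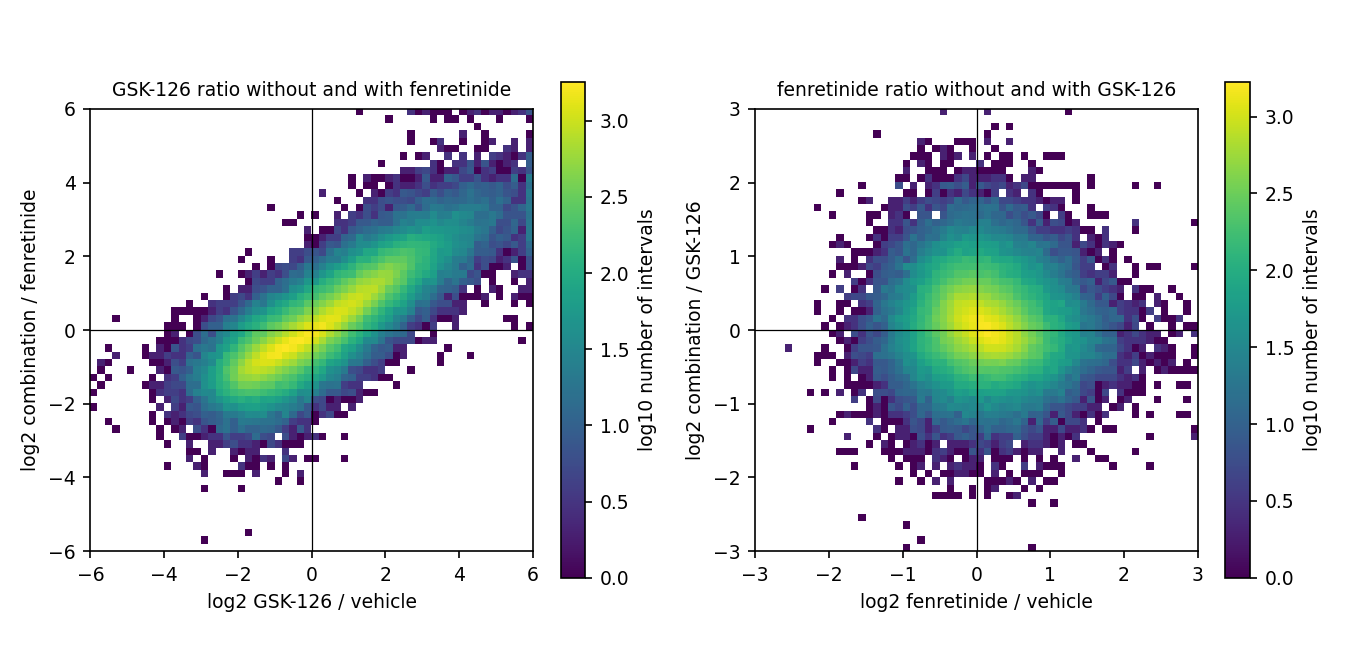
Log2 ratios of 147129 intervals for GSK-126 without (x) and with fenretinide (y), left, and of 127725 intervals for fenretinide without (x) and with GSK-126 (y), right, coloured by log10 number of intervals, with values beyond an axis drawn at its edge. GSK-126 ratios run along the diagonal (r = 0.845) and fenretinide ratios do not (r = -0.126).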

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

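The 2 tests on zinc-finger genes, their grouping and the density over all of them, the scaling of the opposite lists and the test of carried-over GSK-126 fragments were chosen only after the results were seen, and random lists matched on fragments per kb after the data but before their own result were seen.

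The fenretinide medians of 4 gene lists lay on one side of 0 without GSK-126 and on the other with it, with order-statistic intervals that excluded 0, and the differences between the medians were not tested. Almost no single gene passed the 2-fold rule: 0 antigen presentation, protocadherin or housekeeping genes in either comparison, and 2 of 39 ligand genes without and 1 of 36 with GSK-126. Protocadherins and ligands no longer met this rule under any of the 3 other scalings. The median of all genes also went from -0.15 without to 0.08 with GSK-126, and the lists other than protocadherins run the same way. GSK-126 fragments were also split at random in 2 (below). The combination against the second part had a median of 0.24 over genes called lower with the first, and -0.28 over genes called higher. Antigen presentation, ligand and housekeeping lists fell with GSK-126 and protocadherins rose, so the sign changes need not be particular to these lists. Antigen presentation and interferon genes had a log2 median of -0.27 without and 0.23 with GSK-126, a difference of 0.51, the first inside the random lists (percentile 3.47). WNT, BMP and growth factor ligands had -0.39 and 0.17, a difference of 0.56, where the second value lay inside the random lists (percentile 91.0) and its interval met 0 with DESeq2 (-0.10 to 0.13), TMM (-0.08 to 0.14) and background scaling (-0.02 to 0.21). Clustered protocadherins had 0.06 and -0.22, a difference of -0.28, although the first value turned to -0.0652 with DESeq2, -0.0590 with TMM and -0.0758 with background scaling. These genes share intervals, 23 for 44 genes, so their order-statistic intervals (0.0586 to 0.0659 for the first value) are too narrow. Housekeeping genes had -0.30 over 5 genes and 0.29 over 2 genes, a difference of 0.59, both inside the random lists (percentiles 30.6 and 83.8), but the first value was 0.0175 over the gene spans of 2 genes, and with so few genes the interval is their whole range.

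Taken as a set after their values were seen, 244 of 349 zinc-finger genes were higher with GSK-126, 37 lower and 68 neither. Scaling to the fragment total, as far as background scaling corrects it (-0.77 on every log2 ratio), would leave no rise. Yet the median stayed at 1.47, or 1.27 (0.92 to 1.60) over 267 groups of genes that share no interval. No label names a spike-in, so a larger shift, which could cancel the rise, stays open. A flat background left after loss of antibody signal would put these genes at or below the mean fragments per kb of the library, and this stays open: the 238 genes called higher had a median of 1.44 times the mean over their gene span (1.29 to 1.66), but all 341 measured genes had 1.07 (0.842 to 1.20) and their 264 groups that share no interval 0.695 (0.539 to 0.901), from 0.190 with vehicle. The combination against fenretinide, a pair that shares no library with the first, also had a median above 0 (1.71), again with 1 library per condition. A redistribution of the mark by the inhibitor may be a candidate explanation, beside a flat background and scaling to the fragment total.

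The median of developmental genes (HOX, developmental transcription factor and ligand lists together) was lower with fenretinide than that of random lists, although only 3 of 118 genes passed the 2-fold rule. Carried-over GSK-126 fragments as the whole cause would give 1 mixing share everywhere. Yet 45.6% (44.0 to 47.1) of the GSK-126 change was seen at these lists and 31.0% (30.7 to 31.2) at all genes called lower. The share was 5.39% (2.83 to 7.86) at protocadherins and 6.22% (5.98 to 6.46) at all genes called higher with GSK-126. It was 0.343% (-0.153 to 0.827) at ZNF genes, a pool of genes that rose and genes that fell. A small carried-over share as part of the cause stays open. Weaker enrichment of all dense regions would place the lists among random lists of equal fragments per kb, yet their median of -0.40 lay at percentile 0, against -0.17 for random lists. A bias against promoter sequence as the whole cause would lower promoter intervals as far as these lists. Sparse ones had a median of -0.0888 (-0.12 to -0.07) and dense ones -0.21 (-0.22 to -0.19), both below the 0.08 of all intervals. The list median is over genes, and all genes had -0.15, so it cannot be set directly against medians over intervals. Such a bias as part or whole of the cause stays open, and GC content itself was not tested. An effect of fenretinide on these genes may be a candidate explanation, and variation between cultures, which 1 library cannot measure, stays open.

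The combination held smaller GSK-126 changes than GSK-126 alone. Counting error in the GSK-126 library would vanish when its fragments are split at random in 2 and the combination is set against the second part. Yet genes called lower with the first part had a median log2 ratio of the combination against the second part of 0.24. This stood 0.15 above the 0.08 of all genes, and genes called higher with the first part had -0.28. A common share of fragments without the change would shrink falls and rises alike, yet genes called lower kept 89.7% (89.5 to 90.0) and genes called higher 75.0% (74.6 to 75.4), a difference of 14.7 points. Starting from fenretinide, the shares were 85.1% and 73.4%. Both parts come from the same GSK-126 culture and library, so the split removes counting error only. A deviation of that culture or library stays in both parts. It could also make the changes look smaller in the combination, and it stays open. Beside it, a modest opposing effect of fenretinide may remain. Fenretinide alone, against the same vehicle library, went the same way as GSK-126. It held 31.0% of the GSK-126 change at genes called lower and 6.22% at genes called higher. A weaker dose effect of GSK-126 in the combination culture was not tested.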

How the results depend on the processing

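The chromosome 1 to 22 and X restriction, background scaling of list medians, gene span intervals and random lists matched on fragments per kb were chosen only after seeing the data, the last before their own result was seen. No paired analysis was possible because each condition had 1 library. The planned correction for GC content and length was not run. Not every change is called: in simulated data a 3-fold change was called for 44 to 47 of 50 intervals and 45 to 50 of 50 genes. These counts were not split by depth. Restriction to chromosomes 1 to 22 and X moved no interval count by over 1.5 times. Of 452 named gene values, 436 kept their side of the rule with DESeq2, 436 with TMM and 397 with background scaling, and 0 of those past the rule changed direction, while others near a ratio of 1 did. Of 80 list medians, the number that stayed within their own order-statistic interval over genes, which is wide for short lists, was 66 with DESeq2, 66 with TMM, 34 with background scaling, 73 over gene spans and 67 without a distance limit, and 67 of 69 within 2 kb. Random lists matched on fragments per kb left 7 lists outside with GSK-126 (6 otherwise), 4 with fenretinide (6) and 7 with the combination against vehicle (7), 3 against GSK-126 (3) and 4 against fenretinide (4). Among medians outside the random lists, those reversed were protocadherins with fenretinide (-0.0652 with DESeq2, -0.0590 with TMM, -0.0758 with background scaling) and developmental factors for the combination against GSK-126 (0.0108 over gene spans, 0.0437 without a distance limit). Counting medians inside the random lists too, 14 of 80 changed sign under at least 1 setting, among them neuronal genes with fenretinide (0.15 over gene spans). The cause of these and the following shifts was not tested, except where fewer or more features or a looser limit enter by construction.

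Peak overlap of 50% gave 43.2%, 63.2% and 53.6% of vehicle peaks for GSK-126, fenretinide and the combination, 65.1% of GSK-126 peaks and 53.8% of fenretinide peaks for the combination. Equal numbers of top-scoring peaks gave 60.9%, 76.4%, 65.5%, 75.5% and 67.8% in the same order. Peaks at or above the vehicle median score numbered 108015 (vehicle), 79752 (GSK-126), 110528 (fenretinide) and 70729 (combination). With at least 100 fragments in each pair, r was 0.942 for the GSK-126 ratio and -0.282 for the fenretinide ratio.

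With background scaling, higher and lower genes numbered 1067 and 10106 for GSK-126, 27 and 391 for fenretinide, 756 and 10196 for the combination against vehicle, and 690 and 8723 for the combination against fenretinide. Intervals numbered 20175 and 66793, 3100 and 5386, 16254 and 64420, and 11894 and 60310 in the same order. DESeq2 gave 29 and 373 genes for fenretinide and 19 and 106 for the combination against GSK-126, with 3256 and 5229 intervals for fenretinide and 2211 higher intervals for the combination against GSK-126. TMM gave 31 and 366 genes, 22 and 104 genes, 3281 higher intervals and 2357 higher intervals in the same order.

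Without a minimum, higher and lower genes numbered 224 and 483 for fenretinide and 313 and 225 for the combination against GSK-126, with 2258 higher for the combination against vehicle and 2072 against fenretinide. Intervals numbered 8969 and 6581 for fenretinide and 8000 and 6091 for the combination against GSK-126. With a minimum of 100, genes numbered 16 and 123 for fenretinide and 9 and 26 for the combination against GSK-126. Intervals numbered 15284 and 11708 for GSK-126, 204 and 247 for fenretinide, 12873 and 8340 for the combination against vehicle, 38 and 96 against GSK-126, and 10340 and 5176 against fenretinide. With a ratio of 1.5, genes numbered 283 and 1278 for fenretinide and 522 and 333 for the combination against GSK-126, with 7704 lower against vehicle and 6206 lower against fenretinide. Intervals numbered 9910 and 6694 for fenretinide, 6679 and 5039 for the combination against GSK-126, and 32347 lower against fenretinide.

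Within 2 kb, genes numbered 724 and 3071 for GSK-126, 580 and 2472 for the combination against vehicle, 31 and 41 against GSK-126 and 543 and 1280 against fenretinide, with 27 higher for fenretinide. Without a distance limit, higher genes numbered 3273 for GSK-126, 96 for fenretinide, 2948 for the combination against vehicle and 2689 against fenretinide.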

Other observations

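Both tests of starting signal were chosen only after the result was seen.

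Intervals outside chromosomes 1 to 22 and X held 0.344% of vehicle fragments, 1.53% with GSK-126, 0.454% with fenretinide and 1.20% with the combination. An interval on chromosome 16 from 46386206 to 46392025 went from 1664 fragments with vehicle to 28053 with GSK-126, 4744 with fenretinide (ratio 2.58, 2.44 to 2.73) and 24427 with the combination. The largest rise by counting bound with GSK-126 lay on chromosome 1 from 227568560 to 227659674, where 23 fragments became 1922 (88.6, 58.9 to 140.1). By chromosome, the median log2 ratio of intervals with GSK-126 was -1.01 on chromosome 22, -0.88 on 17 and -0.82 on 19, against 1.11 on 21, 0.59 on X and 0.37 on 13. With fenretinide the medians were -0.22, -0.16, -0.14, 0.20, 0.19 and 0.13 in the same order.

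At genes named in advance without an interval within 10 kb, fragments were read over the gene span. EZH2 went from 108 to 31 fragments with GSK-126 (0.304, 0.197 to 0.457), with 133 for fenretinide and 54 for the combination. CDKN1A held 10, 3, 12 and 2 fragments and CDKN2A 0, 3, 1 and 3 in vehicle, GSK-126, fenretinide and combination.

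One hypothesis was that regions of low starting signal gained and dense regions lost with GSK-126, and it stayed undecided. Intervals with a fenretinide peak on chromosomes 1 to 22 and X were placed in 10 groups by fragments per kb in the fenretinide library. The sparsest group had a median log2 ratio of 1.31 (1.29 to 1.33), the ninth -0.70 and the densest -0.44 (-0.46 to -0.41). Interval ends depend on GSK-126 and combination peaks too, which could make a widened interval sparse. Over the 24.3% of these intervals whose ends were both set by fenretinide peaks, the sparsest group was at -0.38 (-0.46 to -0.31), the eighth at -0.94 and the densest at -0.76 (-0.83 to -0.72). No group gained there, but this choice leaves out intervals where a GSK-126 or combination peak reached further. By group, 16.9% to 33.5% of the intervals kept held a GSK-126 or combination peak. The choice itself favours falls, so these values cannot decide the question.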
